A study of Homo sapiens with 101 samples.

How the data were processed

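The deposited values are log2 expression levels that, per the labels, the authors made with RMA (background correction, quantile normalisation between arrays and a summary per probe set). No version is given, nor whether all arrays were normalised together. The values were used without further normalisation.

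The arrays hold SW480 and SW620 cells with a knockdown of CDK5, HRAS, MAP2K1, MAP2K2, MAPK3 or NGFR, an empty vector, a non-target hairpin or no vector. The series description speaks of more knocked-down genes than these 6. Groups were taken from the labels. For HRAS these give 1 hairpin code in replicate 1, another in replicates 3 to 6 and none in replicate 2, so its groups may hold more than 1 hairpin. The other 5 knockdowns have a single code. The source name of the NGFR knockdown SW620 array of replicate 1 is misspelt; it was kept in SW620. Replicates 3 to 6 carry names ending in A1, A2, B1 and B2, and the labels do not say whether these are separate cultures. The non-transduced arrays that the titles call replicate 7 are called replicate 4 in another label field; the titles were followed, and a label series of their own rests on this. Replicate numbers were not taken to pair samples.

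Of 54675 probe sets, 41097 name 1 gene, and 1801 with several genes and 11777 with none were left out. The symbols of 41043 were brought up to date from the reference gene table by identifier, and 54 kept the symbol of the platform. Each of 19775 genes was represented by its brightest probe set over all arrays, a choice that concerned 10523 genes with more than 1. No filter on dim genes was used. No genome was held, so no positions are given.

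All arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust), with terms for group (treatment in each line) and for label series within line, where the 4 styles of sample names define the series. Each knockdown was compared with the mean of both vector controls, averaged over the lines, within each line and as a difference between lines. The vector controls were compared with each other, with non-transduced cells and between lines. Tests are two-sided, with Benjamini-Hochberg adjustment over genes in each comparison and a threshold of 0.05.

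The 20 gene lists hold 413 genes, of which 375 were measured. They were tested with camera at a preset correlation, adjusted over the 120 pairs of list and knockdown, and again with an estimated correlation and with fry. Counts of changed members are adjusted over all genes and over the list alone. The named genes are the targets, the 10 largest rises and 10 largest falls of each knockdown past the threshold with the same sign in both lines, the 3 members with the smallest p of each called list, the 3 largest each way in each difference between lines, and the 10 largest each way for genes shared by all 6 knockdowns and for the control and line comparisons, where these exist. Probe sets without a gene name, open reading frames and unnamed loci were passed over, and fewer may be named, from the top. Groups, comparisons, lists, this rule and most alternatives were set before the data were examined.

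The alternatives were: a replicate block in place of label series, no term for label series, only the compared groups in the model, each vector control alone, the mean of all probe sets, no genes under the 40th percentile of mean level, a second quantile normalisation, arrays averaged in pairs by name ending, replicates 3 to 6 only, and each replicate number left out in turn. Chosen after seeing the data were replicates 1 and 2 only and runs without 3 arrays of degraded RNA (a GAPDH 3 prime minus 5 prime difference over 2), without 3 SW480 arrays that hold genes of SW620, and without all 6.

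The steps were tested on simulated data. Of genes changed by 0.5, 1 or 2 (log2), 91.0%, 100% and 100% were recovered in a knockdown and 55.2%, 92.5% and 100% between lines. Unchanged genes made up 6.73% and 6.78% of these calls. With no change, the highest count over 14 comparisons was 0. Tables were read with data.table (version 1.17.8), splits were run in R, and figures used Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9.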

Results

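SW480 and SW620 are established human colorectal cancer cell lines, SW480 from a primary tumour and SW620 from a lymph node metastasis of the same case. In both lines a short hairpin RNA was aimed at 1 of 6 genes tied to growth signalling. HRAS encodes a RAS GTPase, MAP2K1 and MAP2K2 encode the MEK kinases, and MAPK3 encodes an ERK kinase below them. CDK5 encodes a cyclin-dependent kinase best known from neurons, and NGFR encodes a neurotrophin receptor. Per the labels, the genes that respond to each knockdown were meant for checking a gene network built by computation. Total RNA was hybridised to Affymetrix arrays, 1 sample per array. The arrays fall into 18 groups, 9 treatments in each of the 2 lines. Of these groups, 15 held 6 arrays, the CDK5 knockdown in SW620, which has no replicate 1, held 5, and each non-transduced group held 3. Cells with an empty vector and cells with a non-target hairpin served as the vector controls, 24 arrays in all. Array medians lay between 5.05 and 5.28 on the log2 scale. The sample names follow 4 styles, here called label series: replicate 1 (17 arrays), replicate 2 (18 arrays), replicates 3 to 6 (64 arrays) and replicate 7, which holds only non-transduced cells. Unless stated otherwise, a change is the log2 difference between a knockdown and the vector controls, averaged over both lines and adjusted for label series, ± its standard error. Such a change rests on 12 knockdown arrays, or 11 for CDK5, and it counts as a rise or a fall when its adjusted limma p is under 0.05.

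Averaged over the lines, each of the 6 targeted genes was lower in its own knockdown, which checks the labels. MAP2K2 fell by 1.87 ± 0.23 on the log2 scale to 27.3% of the vector controls, CDK5 (-1.63 ± 0.15) to 32.3% and MAP2K1 (-1.61 ± 0.10) to 32.7%. These 3 genes fell in both lines, below every vector control array of the same line and label series on all of their knockdown arrays. HRAS (-1.30 ± 0.20, 40.6% of control) fell more in SW480 (-1.86 ± 0.28) than in SW620 (-0.74 ± 0.28), a difference between lines of 1.13 ± 0.40 (adjusted p = 0.0369). NGFR (-1.98 ± 0.19) fell to 9.25% of control in SW480 (-3.43 ± 0.26). In SW620, where NGFR stood at 4.99 and 5.19 in the 2 kinds of vector control, near the array medians, against 9.34 and 9.58 in SW480, its level in the knockdown did not pass the threshold (-0.52 ± 0.26, adjusted p = 0.136). The NGFR fall differed between the lines by 2.92 ± 0.37 (adjusted p = 2.64e-09), with little room to fall in SW620, and 4 of 6 SW620 arrays lay below every control against 6 of 6 in SW480. MAPK3 showed the smallest fall of the 6 (-0.45 ± 0.055, 73.0% of control, adjusted p = 2.51e-10). Its probe set is of a kind that can bind related transcripts, and the SW480 array of replicate 1 lay above its controls (0.15). MAP2K2 has 3 probe sets, of which 1 did not change (0.0047 ± 0.064). Some targeted genes also moved in other knockdowns. NGFR fell in the CDK5 knockdown (-0.70 ± 0.19, adjusted p = 0.00487) and in the HRAS knockdown (-0.65 ± 0.19, adjusted p = 0.00317). CDK5 fell in the MAPK3 knockdown (-0.46 ± 0.15, adjusted p = 0.0135) and MAPK3 in the NGFR knockdown (-0.15 ± 0.055, adjusted p = 0.0296). Averaging arrays in pairs ended these 4 calls (adjusted p = 0.134, 0.0535, 0.0853 and 0.218), the comparison with the empty vector alone ended those of NGFR in the CDK5 knockdown and CDK5, and leaving out the term for label series ended those of CDK5 and MAPK3. CDK5 was lower on 7 of these 12 arrays, and its call also ended without the arrays of degraded RNA (-0.21, adjusted p = 0.0975) and without all 6 that stand apart (-0.16, adjusted p = 0.216). The MAPK3 call also ended without replicate 2, 3, 4, 5 or 6 (adjusted p = 0.0679, 0.121, 0.0897, 0.0713 and 0.0888), against the non-target hairpin alone and with arrays quantile normalised again. With replicates 1 and 2 only, 2 of the 6 own-target falls pass the threshold.

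**Figure D1:**
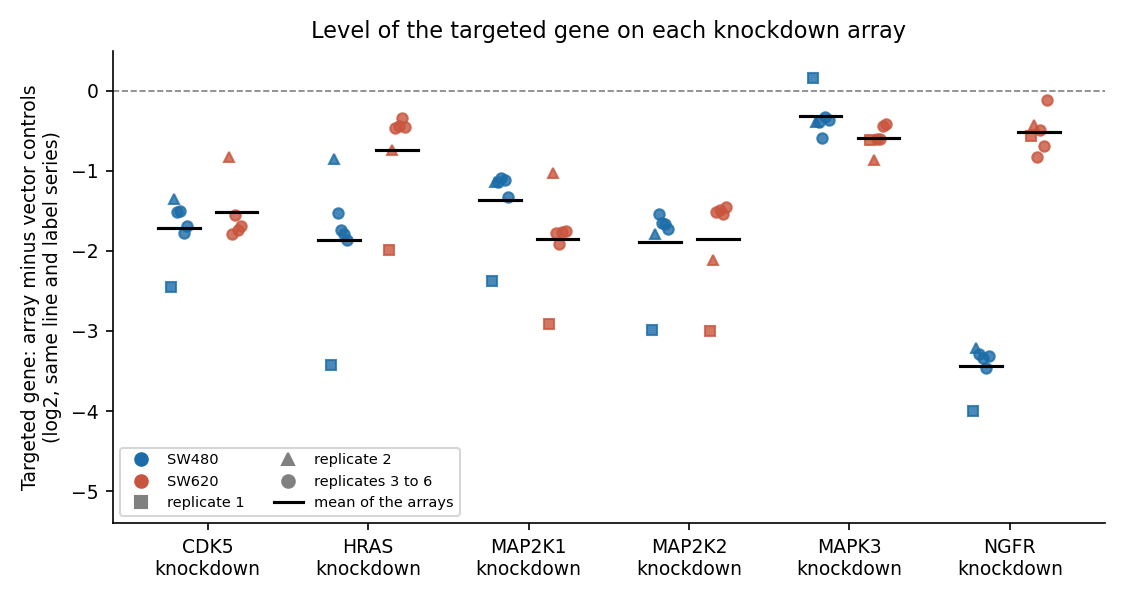
Each point is 1 knockdown array, and its height is the log2 level of the targeted gene minus the mean of the vector controls of the same line and label series; bars are means of the 5 or 6 arrays. Every array lies below 0 apart from the SW480 MAPK3 array of replicate 1 (0.15), and NGFR lies lowest in SW480 (-3.21 to -4.00).

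The HRAS knockdown changed the most genes, 7123 of the 19775 tested (3054 higher and 4069 lower), and the MAP2K1 knockdown the fewest, 3010 (1464 and 1546). CDK5 gave 3840 (1723 higher and 2117 lower), MAP2K2 3794 (1580 and 2214), MAPK3 5067 (2299 and 2768) and NGFR 5681 (2790 and 2891). A change of 2-fold or more was reached by 322 genes for HRAS, 102 for NGFR, 86 for MAPK3, 79 for CDK5, 44 for MAP2K1 and 42 for MAP2K2. Within SW480, the knockdowns of CDK5, MAP2K1, MAP2K2 and MAPK3 changed 1593, 1294, 1022 and 2110 genes. Within SW620 they changed 4742, 3768, 4585 and 5890. HRAS (5180 in SW480 and 6136 in SW620) and NGFR (4746 and 5210) differed less between the lines in this count. The 5210 genes were called although NGFR itself did not pass the threshold in SW620. Of 359 results for single genes that the rule for named genes picks, 258 kept their call without a term for label series and 297 with arrays averaged in pairs, and those that lost it include cell cycle genes such as KIF20A and CCNE2. The labels do not say whether replicates 3 to 6 were separate cultures, and if they were not, every p value given here is too small.

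**Figure D2:**
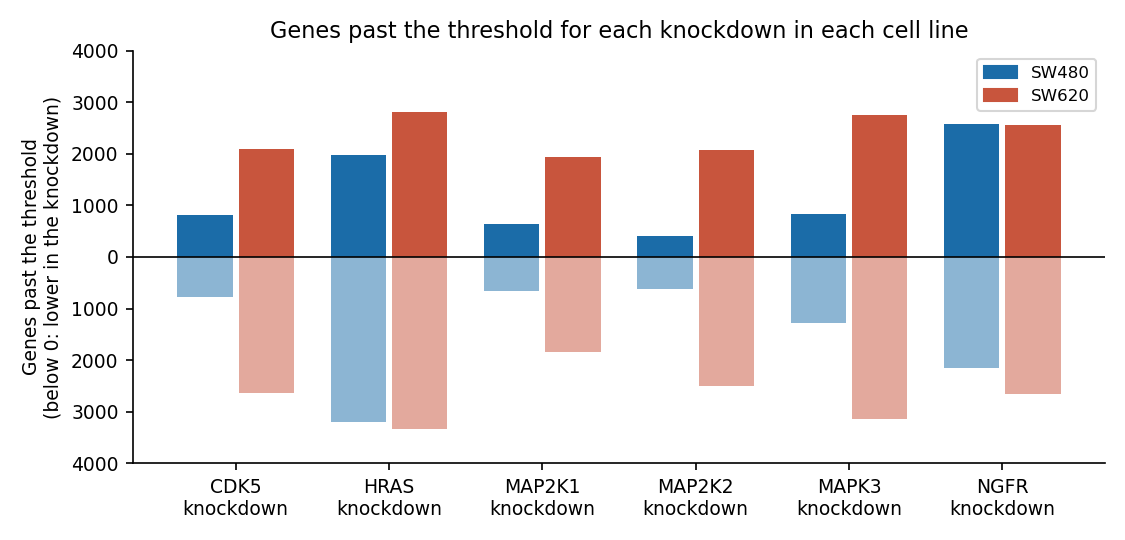
Bars show how many of the 19775 genes passed the threshold in each knockdown and line, upward for higher and downward for lower than the vector controls of that line. The total of both directions is larger in SW620 than in SW480 in all 6 knockdowns (4742 against 1593 for CDK5).

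Genes of mitosis and part of those of DNA replication rose after the CDK5 knockdown, averaged over the lines. Part of the MAPK output, immediate early and amino acid response genes fell. The largest falls included KDELR3 (-1.81 ± 0.14), BET1 (-1.51 ± 0.10) and SQSTM1 (-1.51 ± 0.12). KDELR3 returns proteins to the endoplasmic reticulum, BET1 is a SNARE of the same route, and SQSTM1 is an autophagy receptor. IGFBP1 (-1.76 ± 0.20), SERPINE2 (-1.61 ± 0.19) and CCN2 (-1.46 ± 0.17), which encode secreted proteins, fell as well, as did LY96 (-1.72 ± 0.19), GDA (-1.72 ± 0.23) and TMTC4 (-1.55 ± 0.17). The largest rise was that of DEFA5, an antimicrobial peptide of Paneth cells (2.90 ± 0.32, 4.13 in SW480 and 1.67 in SW620). TNC (1.44 ± 0.25), HAS3 (1.33 ± 0.21), CSGALNACT1 (1.11 ± 0.15) and ISM1 (1.12 ± 0.17) rose too, the first 3 of them genes of the extracellular matrix or its synthesis. So did SYK (1.24 ± 0.18), SSTR1 (1.20 ± 0.18), ITPR2 (1.19 ± 0.18) and PCP4 (1.17 ± 0.14) and the E2F repressor E2F7 (1.19 ± 0.13). All 20 of the largest changes, CDK5 itself included, were seen on 10 or 11 of the 11 arrays. DEFA5 was at 7.23 in replicate 1, which is 1 SW480 array here, 1.30 in replicate 2 and 2.97 in replicates 3 to 6, and is a gene by which SW480 arrays of the MAP2K1 and MAPK3 knockdowns stand apart in replicate 1. TNC was at 0.0035 on that array. In the mitotic G2/M list 26 of 26 rose and 0 fell, with 26 and 0 adjusted over the list alone (adjusted p = 1.51e-18). KIF20A (0.95 ± 0.14) and CDC20 (0.78 ± 0.13) led it (list adjusted p = 0.147, estimated correlation). Of the replication genes (G1/S list) 15 of 23 rose and 0 fell, with 21 and 0 adjusted over the list alone (adjusted p = 1.32e-08). POLA1 (0.52 ± 0.10) and CCNE2 (1.03 ± 0.22) led the list (list adjusted p = 0.336, estimated correlation). In the MAPK output list 12 of 25 fell and 0 rose, with 13 and 0 adjusted over the list alone (adjusted p = 3.14e-07). EMP1 (-1.45 ± 0.19) and LIF (-0.70 ± 0.091) came first (list adjusted p = 0.129, estimated correlation). Of the immediate early genes, 8 of 17 fell and 0 rose, with 8 and 0 adjusted over the list alone (adjusted p = 1.32e-04). IER3 (-0.55 ± 0.08) and ATF3 (-1.04 ± 0.17) led it (list adjusted p = 0.291, estimated correlation). The amino acid response list, targets of ATF4, fell: 13 of 21 fell and 0 rose, with 14 and 1 adjusted over the list alone (adjusted p = 6.64e-08). WARS1 (-0.58 ± 0.071) and SLC7A11 (-1.22 ± 0.18) led the list (list adjusted p = 0.291, estimated correlation). These 5 calls held under all other alternatives chosen beforehand. The medians in SW480 and SW620 had opposite signs for MAPK output (0.038 and -0.65, with 13 of 25 past the test of the difference), immediate early genes (0.048 and -0.43, 7 of 17) and amino acid response (0.17 and -0.85, 17 of 21). Of 20 hypoxia and glycolysis genes 8 fell and 0 rose, with 10 and 0 adjusted over the list alone (adjusted p = 0.00106). NDRG1 (-1.24 ± 0.20) and VEGFA (-1.12 ± 0.20) came first (list adjusted p = 0.336, estimated correlation). In the NF-kB and chemokine list 9 of 18 fell and 0 rose, with 10 and 1 adjusted over the list alone (adjusted p = 3.85e-05). CXCL3 (-0.59 in SW480 and -1.41 in SW620) and CXCL2 (-0.71 ± 0.10) led it (list adjusted p = 0.088, estimated correlation). For Wnt targets 5 of 18 rose and 1 fell, with 8 and 3 adjusted over the list alone (adjusted p = 0.0179). PROX1 (0.77 ± 0.12) and RNF43 (0.64 ± 0.10) led the list (list adjusted p = 0.336, estimated correlation). For cholesterol synthesis 5 of 17 rose and 0 fell, with 10 and 0 adjusted over the list alone (adjusted p = 9.12e-04). ACAT2 (0.81 ± 0.17) came first (list adjusted p = 0.336, estimated correlation). The hypoxia call ended within replicates 3 to 6 and without replicate 2 (adjusted p = 0.406 and 0.838), the cholesterol call within replicates 3 to 6, without replicate 2 and against the non-target hairpin alone (adjusted p = 0.2, 0.133 and 0.153), the Wnt call with the mean of all probe sets and against the non-target hairpin alone (adjusted p = 0.105 and 0.0548) and the NF-kB call without dim genes (adjusted p = 0.0664). Among the 20 genes, calls ended without a term for label series for ITPR2. The count of 3840 genes became 8579 within replicates 3 to 6, 2 within replicates 1 and 2, 817 without a term for label series, 957 with arrays averaged in pairs and 6015 without the 6 arrays that stand apart. It was 2374, 2479, 2380 and 2439 without replicate 3, 4, 5 or 6 in turn, and 5788 without replicate 1.

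The HRAS knockdown lowered part of the epithelial, interferon response, MAPK output and amino acid response genes. Most cell cycle genes rose, but with SW480 medians below 0. Among the 10 largest falls were SERPINA1 (-2.92 ± 0.18), ESRP1 (-2.76 ± 0.17), ANO1 (-2.23 ± 0.25) and SCNN1A (-2.14 ± 0.18). ESRP1 sets epithelial splicing, ANO1 is a chloride channel and SCNN1A a subunit of the epithelial sodium channel. The others were LEMD1 (-2.21 ± 0.35), CST7 (-2.15 ± 0.20), DDIT4 (-2.11 ± 0.28), GSKIP (-2.06 ± 0.10), FGF19 (-2.05 ± 0.20) and TNFSF10 (-2.04 ± 0.22), of which DDIT4 restrains mTOR signalling, FGF19 is a hormone of the ileum and TNFSF10 is a death ligand. The rises were led by TNC (1.71 ± 0.24), SOX2 (1.70 ± 0.19), DEFA5 (1.54 ± 0.31), CADM1 (1.42 ± 0.13) and GALNT10 (1.42 ± 0.13), then DKK1 (1.11 ± 0.22), INF2 (1.14 ± 0.15), ORC6 (1.09 ± 0.16), EIF4E2 (1.09 ± 0.12) and CENPO (1.08 ± 0.15). SOX2 is a transcription factor of stem cells, DKK1 a Wnt antagonist, and ORC6 and CENPO act in replication and at centromeres. Of these 20 genes, 14 moved the same way on all 12 arrays and the others on 10 or 11. DEFA5 was -0.044 and -0.41 in replicates 1 and 2 against 2.43 in replicates 3 to 6, and other probe sets of INF2 fell. The GAPDH 3 prime minus 5 prime difference was 1.39 and 1.47 on the SW480 arrays of replicates 3 and 4 and 0.41 and 0.32 on those of replicates 5 and 6. In deviations from their group mean, these arrays also paired that way (r = 0.576 for replicates 3 and 4, 0.64 for 5 and 6 and -0.803 across), while both r were below 0 in every other group. The labels give another hairpin code for replicate 1 than for replicates 3 to 6. The epithelial list fell: 12 of 19 fell and 0 rose, with 12 and 0 adjusted over the list alone (adjusted p = 9.12e-07). ESRP1 (-2.76 ± 0.17) and CLDN7 (-1.59 ± 0.15) led it (list adjusted p = 0.107, estimated correlation). In the interferon response list 18 of 32 fell and 1 rose, with 18 and 1 adjusted over the list alone (adjusted p = 2.99e-04). OAS1 (-1.23 ± 0.10), IFIH1 (-1.23 ± 0.13) and ISG20 (-1.05 ± 0.11) led the list (list adjusted p = 0.088, estimated correlation). All 3 are sensors or effectors of antiviral defence. Of MAPK output genes 11 of 25 fell and 2 rose, with 12 and 2 adjusted over the list alone (adjusted p = 0.00122). IER3 (-0.97 ± 0.077) and LIF (-0.85 ± 0.088) came first (list adjusted p = 0.336, estimated correlation). In the amino acid response list 14 of 21 fell and 1 rose, with 15 and 2 adjusted over the list alone (adjusted p = 7.71e-05). CEBPB (-1.30 ± 0.15) and DDIT4 (-2.11 ± 0.28) led it (list adjusted p = 0.336, estimated correlation). For G2/M 19 of 26 rose and 0 fell, with 21 and 0 adjusted over the list alone (adjusted p = 9.35e-08). CDC20 (0.90 ± 0.12) and UBE2C (0.59 ± 0.095) led the list (list adjusted p = 0.336, estimated correlation). For G1/S 14 of 23 rose and 0 fell, with 17 and 0 adjusted over the list alone (adjusted p = 1.95e-04). CHAF1A (0.67 ± 0.10) and ORC1 (0.69 ± 0.14) came first (list adjusted p = 0.514, estimated correlation). Medians in SW620 and SW480 were -0.17 and -0.18 for the interferon list and -0.64 and -0.28 for the epithelial list. All 6 calls held under all other alternatives chosen beforehand. The medians in SW480 and SW620 had opposite signs for G1/S (-0.043 and 0.76, with 16 of 23 past the test of the difference), G2/M (-0.08 and 1.07, 23 of 26) and hypoxia and glycolysis (0.024 and -0.58, 7 of 20). In hypoxia and glycolysis 9 of 20 fell and 1 rose, with 11 and 1 adjusted over the list alone (adjusted p = 0.0132). SLC2A1 (-0.74 ± 0.094) and PDK1 (-0.84 ± 0.12) led it (list adjusted p = 0.514, estimated correlation). In oxidative phosphorylation 11 of 25 fell and 0 rose, with 13 and 0 adjusted over the list alone (adjusted p = 0.0192). ATP5F1B (-0.25 ± 0.053) and NDUFS1 (-0.34 ± 0.075) led the list (list adjusted p = 0.514, estimated correlation). Among ribosomal proteins 5 of 15 fell and 0 rose, with 5 and 0 adjusted over the list alone (adjusted p = 0.0295). RPS6 (-0.22 ± 0.032) and RPL32 (-0.17 ± 0.029) came first (list adjusted p = 0.481, estimated correlation). The hypoxia call ended without replicate 2 (adjusted p = 0.467) and under several other settings (adjusted p = 0.0522 to 0.226). The ribosomal call ended without replicate 1 (adjusted p = 0.096) and under several other settings (adjusted p = 0.0522 to 0.174). The oxidative phosphorylation call ended without replicate 1, 3 or 4 (adjusted p = 0.0693, 0.0793 and 0.0836) and under several other settings (adjusted p = 0.0516 to 0.123). Among the 20 genes, calls ended with arrays averaged in pairs for DEFA5 and with the mean of all probe sets for INF2. The count of 7123 genes became 564 within replicates 1 and 2, 2539 without a term for label series and 4257 with arrays averaged in pairs.

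The MAP2K1 knockdown raised mitotic genes and part of the Wnt targets and lowered part of the amino acid response genes. Rises were led by DACH1 (2.04 ± 0.18), KLRC3 (1.72 ± 0.17), RASSF6 (1.71 ± 0.24), PCDH19 (1.58 ± 0.23) and SSTR1 (1.56 ± 0.18), followed by SELENOP (1.48 ± 0.21), ADGRL2 (1.34 ± 0.14), ROBO1 (1.30 ± 0.21), SERPINI1 (1.28 ± 0.23) and SCN3A (1.27 ± 0.18). DACH1 is a transcription factor, PCDH19 a protocadherin, ROBO1 an axon guidance receptor and SELENOP a selenium carrier. The largest falls other than MAP2K1 were SERPINE2 (-1.72 ± 0.18), IGFBP1 (-1.46 ± 0.20), AXL (-1.39 ± 0.23), LY96 (-1.25 ± 0.19) and EMP1 (-1.21 ± 0.18), then BEX2 (-1.22 ± 0.17), LRATD2 (-1.18 ± 0.18), TPRG1L (-1.17 ± 0.069) and KCTD18 (-1.15 ± 0.13). AXL is a receptor tyrosine kinase, and EMP1 is a membrane protein on the MAPK output list. The change was 2.91 in SW480 and 0.25 in SW620 for PCDH19, and -0.13 and -2.79 for IGFBP1. 10 of the 20, among them DACH1, RASSF6, PCDH19 and ROBO1, belong to the genes (83 higher and 37 lower) by which the SW480 arrays of this and the MAPK3 knockdown stand apart in replicate 1. RASSF6 stood at 9.26 there (3.49 in controls) and at 6.50 on the SW480 arrays of this knockdown in replicates 3 to 6. Of these 20 genes, 10 moved the same way on all 12 arrays, and PCDH19 did so on 7. In the G2/M list 24 of 26 rose and 0 fell, with 24 and 0 adjusted over the list alone (adjusted p = 1.12e-19). KIF20A (0.83 ± 0.14) and CDC20 (0.65 ± 0.12) led it (list adjusted p = 0.13, estimated correlation). In the G1/S list 7 of 23 rose and 0 fell, with 12 and 0 adjusted over the list alone (adjusted p = 8.35e-07). CHAF1B (0.39 ± 0.082) and CCNE2 (0.83 ± 0.21) led the list (list adjusted p = 0.345, estimated correlation). Wnt targets rose in both lines (medians 0.31 in SW620 and 0.37 in SW480), as 9 of 18 rose and 0 fell, with 12 and 1 adjusted over the list alone (adjusted p = 3.44e-05, and adjusted p = 0.088, estimated correlation). PROX1 (0.72 ± 0.12) and TNFRSF19 (0.89 ± 0.15) led them. In the amino acid response list 8 of 21 fell and 0 rose, with 11 and 1 adjusted over the list alone (adjusted p = 2.08e-05). CEBPB (-0.87 ± 0.15) and TRIB3 (-0.93 ± 0.16) came first (list adjusted p = 0.336, estimated correlation). These 4 calls held under all other alternatives chosen beforehand. The medians in SW480 and SW620 had opposite signs for G1/S (-0.13 and 0.62, with 13 of 23 past the test of the difference) and amino acid response (0.36 and -0.76, 18 of 21). In the MAPK output list 8 of 25 fell and 0 rose, with 9 and 0 adjusted over the list alone (adjusted p = 3.71e-04). LIF (-0.64 ± 0.088) and EMP1 (-1.21 ± 0.18) led it (list adjusted p = 0.316, estimated correlation). Of the immediate early genes 3 of 17 fell and 0 rose, with 6 and 0 adjusted over the list alone (adjusted p = 0.00136, and adjusted p = 0.336, estimated correlation), namely ATF3 (-1.05 ± 0.16), KLF4 (-0.73 ± 0.15) and IER3 (-0.36 ± 0.077). Both calls ended without replicate 2 (adjusted p = 0.0732 and 0.118), whose SW620 array of this knockdown has a GAPDH difference of 6.04. In hypoxia and glycolysis 6 of 20 fell and 0 rose, with 6 and 0 adjusted over the list alone (adjusted p = 0.0101). PFKFB4 (-0.45 ± 0.092) and NDRG1 (-0.74 ± 0.19) led the list (list adjusted p = 0.497, estimated correlation). For NF-kB 7 of 18 fell and 0 rose, with 8 and 0 adjusted over the list alone (adjusted p = 6.50e-04). CXCL2 (-0.67 ± 0.10) and CXCL3 (-0.74 ± 0.12) came first (list adjusted p = 0.13, estimated correlation). For cholesterol synthesis 6 of 17 rose and 0 fell, with 10 and 1 adjusted over the list alone (adjusted p = 5.69e-04). HSD17B7 (0.20 ± 0.052) and SC5D (0.37 ± 0.10) led it (list adjusted p = 0.336, estimated correlation). The hypoxia call ended within replicates 3 to 6, without replicate 2, against the non-target hairpin alone and without all 6 arrays that stand apart (adjusted p = 0.519, 0.742, 0.095 and 0.0638), the NF-kB call without dim genes (adjusted p = 0.134) and the cholesterol call against the non-target hairpin alone (adjusted p = 0.196). In the oxidative phosphorylation list 1 of 25 rose and 0 fell, with 1 and 0 adjusted over the list alone (adjusted p = 0.0197, and adjusted p = 0.514, estimated correlation). The gene that rose, COX7C (0.37 ± 0.07), also differed between the vector controls. The list turned downward within replicates 3 to 6, and its call ended without replicate 1 or 2 (adjusted p = 0.0888 and 0.926) and under several other settings (adjusted p = 0.0507 to 0.636). Among the 20 genes, calls ended without a term for label series for ROBO1, EMP1 and KCTD18. The count of 3010 genes became 7765 within replicates 3 to 6, 1 within replicates 1 and 2, 329 without a term for label series, 612 with arrays averaged in pairs and 1995 against the non-target hairpin alone. It was 1734, 1728, 1750 and 1699 without replicate 3, 4, 5 or 6 in turn, and 5223 without replicate 1.

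The MAP2K2 knockdown lowered amino acid response genes and part of the MAPK output and immediate early genes, mainly in SW620. Part of the cell cycle genes rose. Of its 42 changes of 2-fold or more, 35 were falls. The largest falls other than MAP2K2 were INHBE (-1.97 ± 0.32), DDIT4 (-1.96 ± 0.28) and TUBB2B (-1.71 ± 0.21), which in SW620 came to -3.75, -3.61 and -2.85 and in SW480 to -0.18, -0.31 and -0.57. PAQR5 (-1.42 ± 0.20), AMIGO2 (-1.32 ± 0.15), CST7 (-1.30 ± 0.20), CBS (-1.29 ± 0.19), SMIM14 (-1.26 ± 0.19) and MSLN (-1.20 ± 0.22) fell as well. CBS makes cystathionine from homocysteine and serine, and MSLN is mesothelin, a surface protein. TNC, a matrix glycoprotein, rose most (1.67 ± 0.24). RASSF6 (1.33 ± 0.24), SOX2 (1.13 ± 0.19), ND6 (1.05 ± 0.19) and GPX2 (0.97 ± 0.24) rose too, ND6 being a gene of the mitochondrial genome and GPX2 a gut glutathione peroxidase, as did the histone genes H2BC12L (1.04 ± 0.22) and H1-2 (0.94 ± 0.20) and SERPINI1 (0.98 ± 0.23), CCDC18 (0.96 ± 0.24) and KLRC3 (0.94 ± 0.17). 5 of these 20 genes moved the same way on all 12 arrays, and SERPINI1, GPX2 and H1-2 did so on 8. PAQR5 was 0.54 in replicate 1 and -2.14 in replicates 3 to 6. The replicate 1 array of this knockdown in SW480 holds high levels of genes of SW620 (a median shift of 3.52 over 29 genes), GPX2 and RASSF6 among them (11.5 and 8.47 against 5.94 and 3.49 in its controls). With SERPINI1, KLRC3, INHBE and CST7 they are also genes by which the SW480 arrays of the MAP2K1 and MAPK3 knockdowns stand apart in replicate 1. In the amino acid response list 16 of 21 fell and 1 rose, with 18 and 1 adjusted over the list alone (adjusted p = 1.10e-13). PHGDH (-0.94 ± 0.12) and CEBPB (-1.11 ± 0.15) led the list (list adjusted p = 0.107, estimated correlation). In the MAPK output list 8 of 25 fell and 0 rose, with 8 and 1 adjusted over the list alone (adjusted p = 1.35e-04). LIF (-0.64 ± 0.088) and EPHA4 (-0.93 ± 0.14) came first (list adjusted p = 0.291, estimated correlation). Of the immediate early genes 9 of 17 fell and 0 rose, with 9 and 1 adjusted over the list alone (adjusted p = 1.28e-04). IER3 (-0.47 ± 0.077), ATF3 (-0.96 ± 0.16) and MCL1 (-0.30 ± 0.066) led it (list adjusted p = 0.291, estimated correlation). In the G2/M list 18 of 26 rose and 0 fell, with 25 and 0 adjusted over the list alone (adjusted p = 1.78e-12). CDC20 (0.74 ± 0.12) and KIF20A (0.75 ± 0.14) led the list (list adjusted p = 0.291, estimated correlation). In the G1/S list 10 of 23 rose and 0 fell, with 14 and 0 adjusted over the list alone (adjusted p = 8.90e-08). SLBP (0.54 ± 0.12) and CCNE2 (0.87 ± 0.21) came first (list adjusted p = 0.336, estimated correlation). These 5 calls held under all other alternatives chosen beforehand. The medians in SW480 and SW620 had opposite signs for G2/M (-0.012 and 0.96, with 19 of 26 past the test of the difference) and hypoxia and glycolysis (0.0086 and -0.37, 6 of 20). They were -0.063 and -1.01 for amino acid response, -0.017 and -0.51 for MAPK output and -0.027 and -0.47 for immediate early genes. Of the hypoxia and glycolysis genes 8 of 20 fell and 0 rose, with 8 and 0 adjusted over the list alone (adjusted p = 2.63e-04). BNIP3L (-0.73 ± 0.12) and VEGFA (-1.12 ± 0.19) led it (list adjusted p = 0.336, estimated correlation). The call was lost within replicates 3 to 6 and without replicate 2 (adjusted p = 0.346 and 0.19). Among epithelial genes 5 of 19 fell and 0 rose, with 5 and 0 adjusted over the list alone (adjusted p = 0.00588). CDS1 (-0.66 ± 0.10) and CLDN7 (-0.81 ± 0.15) led the list (list adjusted p = 0.336, estimated correlation). The call was lost with arrays averaged in pairs (adjusted p = 0.0846). Among Wnt targets 3 of 18 rose and 1 fell, with 5 and 1 adjusted over the list alone (adjusted p = 0.0354). PROX1 (0.91 ± 0.12) and RNF43 (0.51 ± 0.10) came first (list adjusted p = 0.336, estimated correlation). The Wnt call ended without replicate 3, 4 or 6 (adjusted p = 0.0914, 0.0836 and 0.058) and under several other settings (adjusted p = 0.0651 to 0.248). Among the 20 genes, calls ended without a term for label series for SOX2, SERPINI1 and KLRC3, with arrays averaged in pairs for SERPINI1 and within replicates 3 to 6 for H1-2. The count of 3794 genes became 8617 within replicates 3 to 6, 11 within replicates 1 and 2, 627 without a term for label series and 958 with arrays averaged in pairs. It was 2383, 2380, 2300 and 2320 without replicate 3, 4, 5 or 6 in turn.

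Averaged over the lines, the MAPK3 knockdown lowered part of the MAPK output and immediate early genes and raised most mitotic genes. The largest rise was that of ANXA1, a phospholipid-binding protein (2.34 ± 0.25, 1.62 in SW480 and 3.06 in SW620). PCDH19 (1.91 ± 0.23), CALML4 (1.65 ± 0.11), RASSF6 (1.63 ± 0.24) and THBS1 (1.55 ± 0.19) followed. LUM (1.52 ± 0.21) and TNC (1.39 ± 0.24), both matrix genes, and the growth factors BMP5 (1.34 ± 0.11) and BMP2 (1.32 ± 0.15) rose, as did IL20RB (1.31 ± 0.18). For BMP2 the difference was 2.61 in SW480 and 0.037 in SW620. The largest falls were CKAP4 (-1.94 ± 0.15), SERPINA1 (-1.58 ± 0.18), RASGEF1A (-1.51 ± 0.13), ACTA2 (-1.47 ± 0.16) and CAMK2N1 (-1.46 ± 0.26), then GDF15 (-1.44 ± 0.22), H2BC21 (-1.40 ± 0.16), LY96 (-1.35 ± 0.19), TAP2 (-1.30 ± 0.084) and TSPAN5 (-1.29 ± 0.11). CKAP4 is a membrane protein of the endoplasmic reticulum, GDF15 a stress cytokine and TAP2 a subunit of the antigen peptide transporter. CALML4 and BMP5 rose in each label series (1.51, 2.25 and 1.53 for CALML4), whereas THBS1 was -0.19 in replicate 1, 0.34 in replicate 2 and 2.30 in replicates 3 to 6. 7 of the 20 genes moved the same way on all 12 arrays, and BMP2 did so on 8. PCDH19, RASSF6, LUM, BMP2 and IL20RB are among the genes by which this knockdown's SW480 array of replicate 1 stands apart. In the MAPK output list 13 of 25 fell and 0 rose, with 13 and 1 adjusted over the list alone (adjusted p = 1.35e-04). IER3 (-0.69 ± 0.077) and LIF (-0.69 ± 0.088) led it (list adjusted p = 0.291, estimated correlation). Of the immediate early genes 8 of 17 fell and 0 rose, with 10 and 0 adjusted over the list alone (adjusted p = 2.91e-04). IER3 (-0.69 ± 0.077) and ATF3 (-1.04 ± 0.16) led the list (list adjusted p = 0.31, estimated correlation). Mitotic genes rose, as 20 of 26 rose and 0 fell, with 22 and 0 adjusted over the list alone (adjusted p = 1.19e-11). CDC20 (0.82 ± 0.12) and CCNB1 (0.87 ± 0.14) came first (list adjusted p = 0.31, estimated correlation). These 3 calls held under all other alternatives chosen beforehand. The medians in SW480 and SW620 had opposite signs for immediate early genes (0.20 and -0.62, with 13 of 17 past the test of the difference), G1/S (-0.22 and 0.60, 14 of 23), amino acid response (0.23 and -0.57, 18 of 21), intestinal differentiation (0.077 and -0.0029, 4 of 19) and ribosomal proteins (0.023 and -0.33, 9 of 15). In the G1/S list 5 of 23 rose and 0 fell, with 5 and 0 adjusted over the list alone (adjusted p = 0.00364). E2F2 (0.40 ± 0.074) and SLBP (0.51 ± 0.12) led it (list adjusted p = 0.625, estimated correlation). The call was lost with arrays averaged in pairs and with fry (adjusted p = 0.134 and 0.0772). In the intestinal differentiation list 6 of 19 rose and 1 fell, with 6 and 1 adjusted over the list alone (adjusted p = 0.0182, and adjusted p = 0.291, estimated correlation). KRT20 (0.71 ± 0.10), CEACAM6 (0.49 ± 0.071) and CDH17 (0.71 ± 0.11), markers of mature colon cells, led it, and the call ended without dim genes, within replicates 3 to 6 and without replicate 1 (adjusted p = 0.287, 0.127 and 0.147). In hypoxia and glycolysis 9 of 20 fell and 0 rose, with 9 and 0 adjusted over the list alone (adjusted p = 1.95e-04). BNIP3L (-0.85 ± 0.12) and ENO2 (-0.58 ± 0.12) led the list (list adjusted p = 0.336, estimated correlation). Among ribosomal proteins 8 of 15 fell and 0 rose, with 9 and 0 adjusted over the list alone (adjusted p = 0.00364, and adjusted p = 0.336, estimated correlation), by small amounts such as RPS6 (-0.16 ± 0.032). In the amino acid response list 8 of 21 fell and 1 rose, with 8 and 1 adjusted over the list alone (adjusted p = 0.0182). WARS1 (-0.42 ± 0.068) and TRIB3 (-0.67 ± 0.16) came first (list adjusted p = 0.604, estimated correlation). The hypoxia call ended without replicate 2 (adjusted p = 0.12), the ribosomal call within replicates 3 to 6 and without replicate 2 (adjusted p = 0.0637 and 0.153) and the amino acid call without replicate 2 (adjusted p = 0.133) and under several other settings (adjusted p = 0.0516 to 0.221). In replicate 2, this knockdown's SW620 array has a GAPDH difference of 2.95. Among the 20 genes, calls ended without a term for label series for THBS1 and TNC. The count of 5067 genes became 9702 within replicates 3 to 6, 58 within replicates 1 and 2, 1147 without a term for label series and 2134 with arrays averaged in pairs.

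The NGFR knockdown raised part of the mitotic genes and, in SW480, the defensin genes DEFA5 and DEFA6. It lowered amino acid response genes and part of the epithelial and ribosomal protein genes. DEFA5 (3.29 ± 0.31) and DEFA6 (1.90 ± 0.18) stood 5.90 and 3.66 higher in SW480, and 0.68 and 0.14 in SW620. CSGALNACT1 (2.16 ± 0.15), EDN3 (1.95 ± 0.14), SSTR1 (1.73 ± 0.18) and MYH7B (1.70 ± 0.18) rose, as did the histone genes H4C8 (1.67 ± 0.18) and H1-2 (1.66 ± 0.20) and DHRS2 (1.65 ± 0.12) and TNC (1.60 ± 0.24). CSGALNACT1 starts chondroitin sulfate chains and EDN3 is an endothelin. Besides NGFR, the largest falls were TUBB2B (-2.07 ± 0.21), S100P (-1.74 ± 0.23), ASS1 (-1.60 ± 0.22), LRATD2 (-1.56 ± 0.18) and TRIB3 (-1.44 ± 0.16), then TGFBI (-1.44 ± 0.12), CST7 (-1.41 ± 0.20), HS2ST1 (-1.37 ± 0.13) and NT5DC4 (-1.35 ± 0.18). ASS1 makes argininosuccinate, TRIB3 is induced by ATF4, TGFBI is a matrix protein, and S100P binds calcium. Other probe sets of HS2ST1 rose. Of the 20 genes, 17 moved the same way on all 12 arrays, and all 20 kept their call under every alternative chosen beforehand. DEFA5, MYH7B, NGFR and CST7 are also among the genes by which the SW480 arrays of the MAP2K1 and MAPK3 knockdowns stand apart in replicate 1. The genes that are higher there had a median shift of 0.010 on the SW480 array of replicate 1 of this knockdown and of 0.25 to 0.46 in replicates 3 to 6 (-0.074 to 0.046 in vector controls). This knockdown's SW620 array of replicate 1 has a GAPDH difference of 3.82. The amino acid response list fell, as 17 of 21 fell and 0 rose, with 18 and 0 adjusted over the list alone (adjusted p = 1.73e-15). CEBPG (-1.02 ± 0.11) and TRIB3 (-1.44 ± 0.16) led it (list adjusted p = 0.088, estimated correlation). In the epithelial list 6 of 19 fell and 0 rose, with 8 and 0 adjusted over the list alone (adjusted p = 0.00122). CLDN7 (-1.21 ± 0.15) and ESRP1 (-1.20 ± 0.17) led the list (list adjusted p = 0.317, estimated correlation). Ribosomal protein genes fell by small amounts, as 7 of 15 fell and 0 rose, with 7 and 0 adjusted over the list alone (adjusted p = 7.32e-04). RPL3 (-0.39 ± 0.053) and RPS6 (-0.17 ± 0.032) came first (list adjusted p = 0.316, estimated correlation). Mitotic genes rose, as 18 of 26 rose and 0 fell, with 19 and 0 adjusted over the list alone (adjusted p = 4.37e-08). CENPF (0.69 ± 0.13) and CDC20 (0.60 ± 0.12) led it (list adjusted p = 0.336, estimated correlation). In the G1/S list 6 of 23 rose and 0 fell, with 9 and 0 adjusted over the list alone (adjusted p = 5.37e-04). E2F2 (0.35 ± 0.074) and CCNE2 (0.90 ± 0.21) led the list (list adjusted p = 0.546, estimated correlation). These 5 calls held under all other alternatives chosen beforehand. The medians in SW480 and SW620 had opposite signs for MAPK output (0.016 and -0.54, with 13 of 25 past the test of the difference) and G1/S (-0.14 and 0.71, 19 of 23). In the MAPK output list 10 of 25 fell and 0 rose, with 11 and 1 adjusted over the list alone (adjusted p = 0.00364). ETV4 (-0.93 ± 0.12) and LIF (-0.70 ± 0.088) came first (list adjusted p = 0.336, estimated correlation). The call was lost within replicates 3 to 6 and without the 3 arrays of degraded RNA (adjusted p = 0.316 and 0.0591). Of the Wnt targets 7 of 18 rose and 3 fell, with 7 and 3 adjusted over the list alone (adjusted p = 0.0463). RNF43 (0.94 ± 0.10) and APCDD1 (1.04 ± 0.18) led it (list adjusted p = 0.345, estimated correlation). This call ended without replicate 3, 4, 5 or 6 (adjusted p = 0.191, 0.152, 0.212 and 0.111) and under several other settings (adjusted p = 0.0507 to 0.487). Within replicates 1 and 2, APCDD1 was -0.11. In hypoxia and glycolysis 8 of 20 fell and 1 rose, with 10 and 1 adjusted over the list alone (adjusted p = 0.00633). PDK1 (-0.72 ± 0.12) and BNIP3L (-0.64 ± 0.12) led the list (list adjusted p = 0.472, estimated correlation). The call was lost within replicates 3 to 6 and without replicate 2 (adjusted p = 0.179 and 0.246).  The count of 5681 genes became 10544 within replicates 3 to 6, 315 within replicates 1 and 2, 1348 without a term for label series and 2730 with arrays averaged in pairs.

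Against the vector controls, all 6 knockdowns shared a set of changes. In SW620, by medians not tested as sets, mitotic genes were higher and amino acid response genes lower. The same direction in all 6 was found for 360 genes, 141 higher and 219 lower, where independent lists of these sizes would share 0.104. As all 6 share their controls, the count was repeated with 3 knockdowns against the empty vector and 3 against the non-target hairpin. It was then 174, or 164 with the controls exchanged. It was 0 in each of 20 simulated data sets, whose groups do not differ, so differences between cultures are not covered. Higher in all 6 were TNC (1.47, range 1.03 to 1.71), THBS1 (1.33, range 0.92 to 1.99), SOX2 (1.08, range 0.62 to 1.70), SHCBP1 (0.90, range 0.71 to 1.08) and EIF4E2 (0.90, range 0.79 to 1.09), given as the mean of the 6 changes, followed by BMP2, ND6, PCLAF, DEF8 and MKI67, a marker of dividing cells. Lower in all 6 were DDIT4 (-1.61, -2.11 to -1.02), CST7 (-1.36, -2.15 to -0.93), IGFBP1 (-1.32, -1.76 to -0.73), LRATD2 (-1.29, -1.95 to -0.82) and BEX2 (-1.27, -1.82 to -1.02). Then came ASS1, SERPINA1, SERPINE2, GDF15 and RASGEF1A. DDIT4 averaged -3.24 in SW620 and 0.014 in SW480, and THBS1 averaged 2.53 and 0.13. TNC (1.49 and 1.46) and EIF4E2 (0.82 and 0.98) rose similarly in both lines, and BMP2 averaged -0.026 and 1.65. In SW620, the G2/M list had medians of 0.96 to 1.16 across the 6 knockdowns and the amino acid response list -1.28 to -0.57, against -0.080 to 0.16 and -0.17 to 0.36 in SW480. In label series, the SW620 G2/M medians were 0.24 to 1.67 in replicate 1, 1.96 to 2.80 in replicate 2 and 0.60 to 0.84 in replicates 3 to 6. The amino acid response medians were -1.97 to -0.092, -1.16 to -0.79 and -1.12 to -0.56. Across genes, which are not independent replicates, the log2 changes of the 15 pairs of knockdowns correlated with a mean r of 0.448 (0.28 to 0.59) when each of a pair had its own kind of vector control, against a mean of -0.022 and at most 0.417 for a pair in simulated data. Of the 120 pairs of a list and a knockdown, 52 passed the test with the preset correlation, 0 with an estimated correlation and 66 with fry, which asks whether the genes of a list move 1 way and does not compare them with other genes. Other splits of the same arrays gave a median of 25 and at most 49 passes with the preset correlation. The lists for p53 targets, the unfolded protein response, mesenchymal genes, and markers of fibroblasts, of blood and endothelium and of neurons and glia passed in no knockdown by camera (lowest adjusted p 0.316, 0.316, 0.145, 0.292, 0.467 and 0.234). By fry they passed in 1 to 3 knockdowns (lowest adjusted p 0.00351, 0.0479, 0.00296, 0.015 and 0.0131), except for blood and endothelium (0.217). The count of 360 became 1709 within replicates 3 to 6, 0 within replicates 1 and 2, 35 without a term for label series, 26 with arrays averaged in pairs, 212 against the empty vector alone and 638 without the 6 arrays that stand apart. It was 147, 160, 151 and 148 without replicate 3, 4, 5 or 6, and 1021 without replicate 1.

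**Figure D3:**
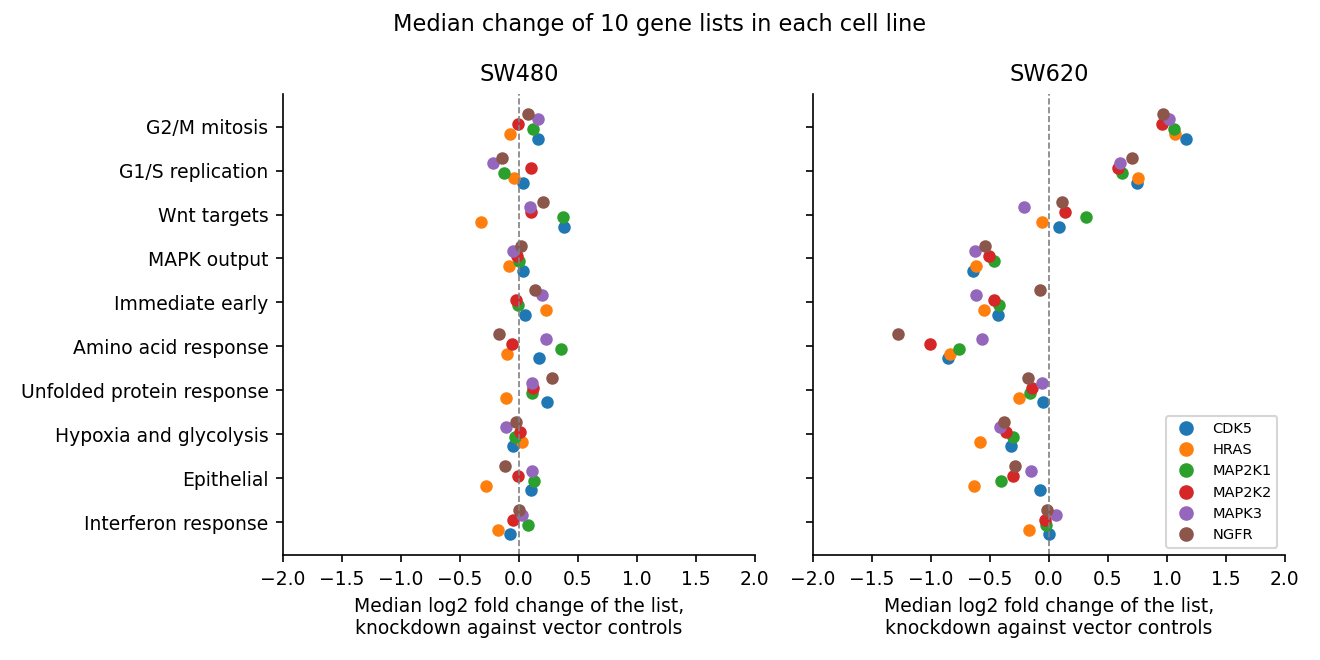
Each point is the median log2 change of 1 gene list in 1 knockdown against the vector controls of the same line, for 10 of the 20 lists. In SW620 all 6 knockdowns lie at 0.96 to 1.16 for G2/M mitosis, whereas the SW480 points lie between -0.080 and 0.16.

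The knockdown effects differed between the lines for many genes, by the test of the difference itself (effect in SW620 minus effect in SW480). This test passed for 4693 genes with NGFR, 3732 with HRAS, 3363 with MAPK3, 3076 with CDK5, 2282 with MAP2K1 and 2064 with MAP2K2. Of these, 549, 263, 171, 133, 92 and 53 passed the threshold in both lines with opposite signs. In the amino acid response list, the test of the difference passed for 15 to 19 of 21 genes in each knockdown. Single genes with lower effects in SW620 were INHBE for NGFR (-4.06 ± 0.64), MAP2K1, CDK5 and MAP2K2, ASNS for MAP2K1 (-3.48 ± 0.44) and NGFR, and DDIT4 for MAP2K1 (-3.71 ± 0.55), MAPK3 and MAP2K2. In the CDK5 knockdown, GDF15 (-3.11 ± 0.45) and LEMD1 (-3.63 ± 0.72) had lower effects in SW620 as well, and so had IGFBP1 for HRAS (-3.20 ± 0.39) and MAP2K2. THBS1 had higher effects in SW620 for HRAS (4.22 ± 0.37), CDK5 and MAP2K2, and GASK1B for MAPK3 (4.05 ± 0.33), CDK5 and MAP2K1. The HRAS knockdown moved TNFRSF11B, the decoy receptor osteoprotegerin, by -3.24 in SW480 and 1.10 in SW620, and fibronectin FN1 by -1.50 and 2.59. In the MAPK3 knockdown DACH1 stood 2.92 higher in SW480 and -0.78 in SW620, and DNAJC12 2.51 and -0.52, and both are genes by which the SW480 array of replicate 1 stands apart. With NGFR, AK5 (2.55 ± 0.20) was higher in SW620. In at least 1 of these knockdowns, the call of the difference ended without a term for label series for THBS1 and GASK1B, and with arrays averaged in pairs for LEMD1, GASK1B, THBS1, INHBE and DDIT4. The 6 counts, in the order given first, became 9294, 9934, 8252, 9098, 8539 and 9374 within replicates 3 to 6, 2, 0, 5, 0, 0 and 0 within replicates 1 and 2, 901, 380, 389, 430, 191 and 254 without a term for label series, and 1311, 564, 588, 250, 90 and 99 with arrays averaged in pairs. Without all 6 arrays that stand apart, those of HRAS, CDK5 and MAP2K2 became 6025, 5330 and 3684. Without replicate 3, 5 or 6 in turn, the count was 2923, 3030 and 2904 for NGFR. Without replicate 1, 3, 4, 5 or 6 in turn, the count was 5819, 1757, 1747, 2405 and 2419 for HRAS; 5279, 2016, 1946, 1889 and 1888 for MAPK3; and 4996, 1465, 1432, 1510 and 1338 for CDK5. Without replicate 1, 2, 3, 4, 5 or 6 in turn, the count was 4636, 4067, 757, 911, 817 and 748 for MAP2K1; and 4800, 4015, 742, 784, 806 and 687 for MAP2K2.

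The vector controls were compared with each other and with cells that carried no vector, to see what changes with the vector and with a hairpin that has no target. The non-target hairpin changed 17 genes against the empty vector, 16 lower and 1 higher, while 950 passed an unadjusted p of 0.05. The largest falls were TULP3 (-1.05 ± 0.10), CCDC90B (-0.85 ± 0.11), FAM234B (-0.74 ± 0.11), SKA2 (-0.64 ± 0.11) and COX7C (-0.63 ± 0.081), then ARPC3 (-0.61 ± 0.088), MGAT4B (-0.59 ± 0.078), SEMA4D (-0.56 ± 0.10), ANKRD40 (-0.49 ± 0.085) and PPCS (-0.47 ± 0.091), of which COX7C is a subunit of cytochrome oxidase and ARPC3 of an actin-nucleating complex. HSD17B2 (0.70 ± 0.13) was the only rise among the 17. These 10 falls were seen on 12 of 12 arrays, and HSD17B2 was higher on 10 of 12. Without a term for label series, FAM234B and COX7C kept their call, and arrays averaged in pairs ended those of HSD17B2, SKA2, SEMA4D, ANKRD40 and PPCS. The call of HSD17B2 also ended without replicate 3, 5 or 6, and those of SKA2 and MGAT4B with the mean of all probe sets. The count became 2110 within replicates 3 to 6, 0 within replicates 1 and 2, 2 without a term for label series, 6 with arrays averaged in pairs, and 66, 43 and 128 without the degraded, the SW480 or all 6 of the arrays that stand apart. It was 45 and 82 without replicate 1 or 2, and 11, 11, 10 and 11 without replicate 3, 4, 5 or 6. Against non-transduced cells, the vector controls differed in 422 genes, 283 higher and 139 lower. The largest rises were TSPAN8 (1.67 ± 0.39), S100P (1.49 ± 0.37), ERRFI1 (1.47 ± 0.24), MAFF (1.46 ± 0.25) and EMP1 (1.45 ± 0.28), then AKAP12 (1.43 ± 0.29), JAG1 (1.43 ± 0.22), CDKN2B (1.41 ± 0.33), KLF4 (1.31 ± 0.24) and SERPINE2 (1.29 ± 0.29). ERRFI1 and MAFF are induced by growth factors, JAG1 is a Notch ligand, and CDKN2B is a cell cycle inhibitor. The largest falls were ND6 (-1.33 ± 0.30), FTX (-1.25 ± 0.24), MYH7B (-1.16 ± 0.28), LMNB1 (-1.11 ± 0.21) and PTPRO (-1.10 ± 0.24), then CBX5 (-1.07 ± 0.24), ITPR2 (-1.07 ± 0.27), ANKRD36B (-1.07 ± 0.30), MKI67 (-0.997 ± 0.28) and TAF15 (-0.93 ± 0.23). Of 17 immediate early genes 4 rose, and 14 adjusted over the list alone. Of 26 G2/M genes 4 fell, and 15 adjusted over the list alone. These lists were not tested as sets here. The difference was 2.82 in SW620 and 0.10 in SW480 for MAFF, and -1.34 and -0.65 for MKI67. Of the 20 genes, 19 moved the same way on all 4 arrays of non-transduced cells that share a label series with vector controls, and MAFF on 3. None of the 20 calls held under every alternative chosen beforehand. They ended without a term for label series for all but ERRFI1 and with arrays averaged in pairs for all but ERRFI1, MAFF, JAG1 and KLF4. Leaving out replicate 1 ended those of S100P, ERRFI1, ITPR2 and ANKRD36B, replicate 2 that of PTPRO, replicate 3, 4, 5 or 6 those of S100P, ITPR2, ANKRD36B, MKI67 and TAF15, replicate 3, 4 or 6 that of MYH7B, replicate 6 that of TSPAN8, and a replicate block those of ANKRD36B and MKI67 (adjusted p = 0.0557 and 0.0570). The count became 6 without a term for label series, 0 within replicates 1 and 2, 13 with arrays averaged in pairs, 279 with a replicate block, and 1029 and 1401 without the degraded or all 6 of the arrays that stand apart. It was 1591 and 2280 without replicate 1 or 2 and 130, 126, 136 and 118 without replicate 3, 4, 5 or 6, and MKI67 turned to 0.12 without replicate 1.

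SW620 and SW480 differed in 9607 of 19775 genes in the vector controls, 4726 higher and 4881 lower in SW620, and 1762 of them by 2-fold or more. Highest in SW620 were TOX3 (6.89 ± 0.21), AKR1C3 (6.19 ± 0.32), DNAJC12 (5.97 ± 0.24), RASSF6 (5.70 ± 0.28), CLRN3 (5.59 ± 0.27) and PROM1 (5.39 ± 0.20). PROM1 is a stem cell surface protein, and AKR1C3 reduces steroids. Lowest in SW620 were PHLDB2 (-6.81 ± 0.21), KRT5 (-6.33 ± 0.13), WNT5A (-6.23 ± 0.23), MAL2 (-6.21 ± 0.17) and DCLK1 (-5.75 ± 0.28), then EPAS1 (-5.59 ± 0.21) and KRT13 (-5.45 ± 0.25). KRT5 and KRT13 are keratins of stratified epithelia, WNT5A is a Wnt ligand and EPAS1 a hypoxia-inducible factor. Cell cycle genes were lower in SW620 in these controls: 24 of 26 G2/M genes and 21 of 23 G1/S genes fell below SW480, by medians of -1.04 and -0.72. Of 21 amino acid response genes, 17 were higher and 1 lower, with a median of 0.92. These lists were not tested as sets in this comparison. The named genes differed the same way in each label series (7.35, 6.05 and 5.90 for TOX3 in replicates 3 to 6, 1 and 2). The count became 5361 without a term for label series and 2521 within replicates 1 and 2.

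Some arrays stood apart from the rest of their group. On 3 SW620 arrays the GAPDH probe sets at the 3 prime end lay 6.04, 3.82 and 2.95 above those at the 5 prime end, for MAP2K1 in replicate 2, NGFR in replicate 1 and MAPK3 in replicate 2. This is a sign of degraded RNA, and all other arrays stayed at or under 1.47. 3 SW480 arrays of replicate 1 held genes that are high in SW620. In the MAP2K2 knockdown none of the 29 genes that lie over 3 higher in SW620 was within the range of the SW480 controls (median shift 3.52), among them PROM1 (7.84 against 3.43) and PEG10 (6.69 against 4.17). In the MAP2K1 and MAPK3 knockdowns RASSF6, GPX2 and AKR1C3 were higher too (9.26 and 9.23 for RASSF6 against 3.49), while PROM1 stayed at 3.30 on both arrays, and DEFA5 (8.59 and 11.9 against 5.33) and DKK4 (9.76 and 11.4 against 5.05) stood above their level in the controls of either line. The genes named for these 3 arrays were chosen after their values were seen. A shift common to the SW620 knockdown arrays of replicates 3 to 6 was followed over 200 genes chosen there, with a score of 1 for its mean size. On replicate 1 arrays the score was 0.0079 for MAP2K1, -0.097 for MAP2K2 and -0.0027 for MAPK3, but 0.71 for HRAS and 0.68 for NGFR. On replicate 2 arrays it was 0.41 to 0.69 for all 6 knockdowns. Vector controls scored -0.034 and 0.034, equal and opposite by construction. Non-transduced SW620 cells scored 0.76, 0.020 and 0.54 in replicates 1, 2 and 7.

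**Figure D4:**
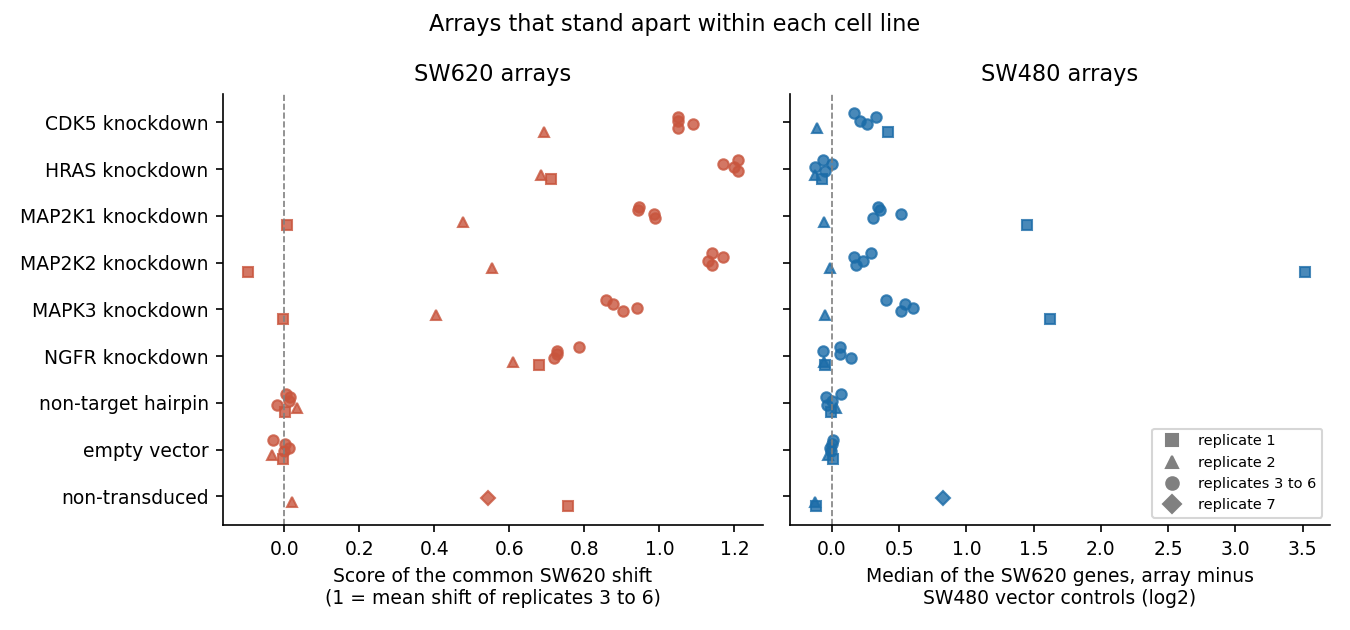
Each point is 1 array. On the left is the score of the common shift in SW620. By construction, knockdown arrays of replicates 3 to 6 average 1 and vector controls of a series 0. On the right is the median log2 shift of 29 genes of SW620 in the SW480 arrays. The replicate 1 arrays of MAP2K1, MAP2K2 and MAPK3 score near 0 on the left and lie farthest right in SW480, with 3.52 for MAP2K2.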

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

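All tests of explanations in this part and the set of 29 genes of SW620 were chosen after the patterns were seen.

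Arrays that stand far from their group were found 15 times among 44 groups and measures checked, where chance gives about 1 in 20. In SW620 the GAPDH difference was 6.04 for MAP2K1 and 2.95 for MAPK3 in replicate 2 and 3.82 for NGFR in replicate 1. The target stood at -0.83 against the vector controls for CDK5 in SW620 replicate 2, and at -1.99 for HRAS in SW620 replicate 1. In SW480 replicate 1 it stood at -2.38 for MAP2K1, -2.99 for MAP2K2, 0.15 for MAPK3 and -4.00 for NGFR. The median shift of the 29 genes was 3.52 for MAP2K2 in SW480 replicate 1. In SW620 it was 0.022 for CDK5, 0.24 for MAP2K2 and 0.46 for MAPK3 in replicate 2, and -0.82 for HRAS and -1.06 for NGFR in replicate 1.

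By the test of the difference itself the lines differed for 3076 (CDK5), 3732 (HRAS), 2282 (MAP2K1), 2064 (MAP2K2), 3363 (MAPK3) and 4693 genes (NGFR). The fall of the target differed by 1.13 for HRAS and by 2.92 for NGFR, whose controls in SW620 (4.99 and 5.19) leave little room for a fall.

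In replicate 1, 3 SW480 knockdown arrays held genes that are high in SW620. For MAP2K1 and MAPK3, SW620 RNA or cells mixed in is argued against, since 7 and 8 of the 29 genes stayed within the range of the SW480 controls. For MAP2K2 a mixture stays open as a hypothesis, since 0 of the 29 did, though DKK4 stood above its controls in either line (8.50 against 5.05 and 4.82), and a swap with the SW620 array is argued against for all 3, as 0 of those SW620 arrays had a lower mean of SW620 than of SW480 genes. The knockdown as the whole cause for MAP2K1 and MAPK3 is argued against by replicate 2, where the 83 genes over 2 higher on both arrays had median shifts of -0.0099 and -0.096, though in replicates 3 to 6 these shifts were 0.93 to 1.02 and 0.71 to 0.94, 0.49 to 0.59 for CDK5, 0.50 to 0.58 for MAP2K2, 0.25 to 0.46 for NGFR, -0.22 to 0.024 for HRAS and -0.074 to 0.046 for the vector controls. A state that SW480 cells may take without a hairpin stays open for the rises. Non-transduced SW480 cells of replicate 7 showed a median shift of 1.42 (against the controls of replicates 3 to 6). The 37 genes over 2 lower had a median of -0.13 there, against -2.28 and -2.91 on the MAP2K1 and MAPK3 arrays. A part played by the knockdown was not excluded.

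In SW620, the 6 knockdowns shared a shift, followed over 200 genes, 53 of which are among the genes shared by all 6 in both lines together. A response to any hairpin that lowers its target is argued against as the whole cause, as 3 knockdown arrays of replicate 1 (MAP2K1, MAP2K2 and MAPK3) scored near 0 with their target below every control, although on replicate 2 arrays all 6 scored 0.41 to 0.69 and the vector controls -0.034 and 0.034. Degraded RNA is argued against, as the GAPDH difference of knockdowns and vector controls in replicates 3 to 6 lay 0.344 SD apart (0.365 against 0.335). A culture state that may arise apart from any hairpin stays open, since the scores of the 3 non-transduced arrays spanned 0.737, where the vector controls of a label series lay at most 0.068 apart. Replicate 2, where non-transduced cells scored 0.020, goes with a response to the knockdowns, which was not excluded as a part of the shift, and the hypothesis was found and tested on the same data.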

How the results depend on the processing

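Runs without the arrays that stand apart and with replicates 1 and 2 only were chosen after seeing the data. With the arrays quantile normalised again no count moved beyond 1.5-fold, no direction turned, and 2 of the 52 list calls were lost. Of 359 results for single genes, 235 kept sign and call under every alternative chosen beforehand, and of 52 list calls 28 did so under all but the estimated correlation, which left 0. With a replicate block, in which replicate number replaces the label series, 357 of 359 genes and all 52 lists kept their call, and the vector controls differed from non-transduced cells in 279 genes. Once group and label series were removed, arrays of the same replicate number correlated above 0.1 in 19.0% of pairs in SW480 and 22.2% in SW620 (lowest r -0.69 and -0.70), so numbers were not used as pairs. Counts of called genes follow in the order CDK5, HRAS, MAP2K1, MAP2K2, MAPK3 and NGFR, and the cause was not tested unless said. Without a term for label series they were 817, 2539, 329, 627, 1147 and 1348 for the 6 knockdowns, 430, 380, 191, 254, 389 and 901 for the difference between lines, 2 for the non-target hairpin, 6 for the non-transduced cells, 5361 for the 2 lines and 35 for the genes shared by all 6. With arrays averaged in pairs, which leaves fewer values per group, they were 957, 4257, 612, 958, 2134 and 2730 for the 6 knockdowns, 250, 564, 90, 99, 588 and 1311 for the difference between lines, 6 for the non-target hairpin, 13 for the non-transduced cells and 26 for the genes shared by all 6. Within replicates 3 to 6 they were 8579, 7765, 8617, 9702 and 10544 for CDK5, MAP2K1, MAP2K2, MAPK3 and NGFR, 9098, 9934, 8539, 9374, 8252 and 9294 for the difference between lines, 2110 for the non-target hairpin and 1709 for the genes shared by all 6, and this setting gives no value for non-transduced cells. Within replicates 1 and 2, 58 of 359 genes kept their call, 2 of the 6 falls of target genes passed, the mean correlation was 0.367, and the counts were 2, 564, 1, 11, 58 and 315 for the 6 knockdowns, 0, 0, 0, 0, 5 and 2 for the difference between lines, 0 for the non-target hairpin, 0 for the non-transduced cells, 2521 for the 2 lines and 0 for the genes shared by all 6. With only the compared groups in the model they were 7682 and 5762 for CDK5 and MAP2K2, 7508, 5885, 3771 and 3836 for the difference between lines of CDK5, HRAS, MAP2K1 and MAP2K2, 1437 for the non-target hairpin, 2969 for the non-transduced cells and 718 for the genes shared by all 6. Against the non-target hairpin alone they were 1995 for MAP2K1 and 1727, 1984, 1086, 994 and 2015 for the difference between lines of CDK5, HRAS, MAP2K1, MAP2K2 and MAPK3; against the empty vector alone, 212 for the genes shared by all 6; without dim genes, 1359 for the difference between lines of MAP2K2. Without the arrays of degraded RNA they were 3379 for the difference between lines of MAP2K2, 66 for the non-target hairpin and 1029 for the non-transduced cells; without the 3 SW480 arrays, 43 for the non-target hairpin; without all 6 arrays, 6015 for CDK5, 5330, 6025 and 3684 for the difference between lines of CDK5, HRAS and MAP2K2, 128 for the non-target hairpin, 1401 for the non-transduced cells and 638 for the genes shared by all 6. Leaving out 1 replicate number at a time gave 2374 to 5788, 5569 to 8132, 1699 to 5223, 2300 to 5691, 3578 to 7465 and 4146 to 7460 for the 6 knockdowns, 1338 to 4996, 1747 to 5819, 748 to 4636, 687 to 4800, 1888 to 5279 and 2904 to 6221 for the differences between lines, 10 to 82 for the non-target hairpin, 118 to 2280 for the non-transduced cells, 147 to 1021 for the genes shared by all 6, 44 to 52 for the lists, and 0.393 to 0.495 for the mean correlation (standard error 0.0669). 10 results turned direction, and none of them passed the threshold after the turn: the oxidative phosphorylation list in the MAP2K1 knockdown (adjusted p = 0.577) within replicates 3 to 6; MKI67 in the vector controls without replicate 1 (-2.02 to 0.12 over the replicates left out); and, within replicates 1 and 2, the epithelial list for MAP2K2 (adjusted p = 0.888), the G1/S list for MAPK3 (adjusted p = 0.452), the Wnt list for NGFR (adjusted p = 0.109), DEFA5 for HRAS (-0.23), PAQR5 and MCL1 for MAP2K2 (0.029 and 0.035), E2F2 for MAPK3 (-0.077) and APCDD1 for NGFR (-0.11). Probe sets near background limit what can be seen: 320 of the 359 genes stayed without dim genes, and all 320 kept their call.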

Other observations

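The other splits and the agreement between label series in this part were chosen after the results were seen.

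Non-transduced SW620 cells of replicates 1, 2 and 7 stood at 1.99, 0.54 and 0.48 for the median of the G2/M list against the vector controls (for replicate 7, those of replicates 3 to 6), at -1.57, 0.14 and -0.16 for the amino acid response list, and at -0.70, -0.81 and -0.59 for the MAPK output list, whose medians in the SW620 knockdowns were -0.65 to -0.46.

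The early label series agreed unevenly with the later one. Of the genes past the threshold and at least 2-fold changed within replicates 3 to 6, the share with the same sign on the SW480 arrays of replicates 1 and 2 was 64.6% and 74.3% for CDK5, 94.4% and 87.2% for HRAS, 79.0% and 66.1% for MAP2K1, 51.5% and 61.4% for MAP2K2, 55.7% and 82.6% for MAPK3, and 96.2% and 93.3% for NGFR. On SW620 arrays it was 58.4% to 92.9%. Across genes, which are not independent replicates, the later response matched the early arrays of another knockdown better than its own for MAP2K2 in SW480 (r 0.121 against -0.0142) and, in SW620, for MAP2K1 (0.543 against 0.226), MAP2K2 (0.499 against 0.27), MAPK3 (0.461 against 0.233) and NGFR (0.456 against 0.342). Without the arrays that stand apart this also held for MAP2K1 in SW480 (0.187 against -0.202).

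Each comparison was refitted on its own arrays with groups exchanged within line and label series, or, for the lines, with lines exchanged within label series and kind of vector. In each comparison below, 1 of 100 drawn splits, the real one, gave as many genes, so chance can be excluded if the arrays are independent. For replicates 3 to 6 the labels do not show this, and chance between cultures was not excluded. The real and highest other counts were 7451 and 1108 for CDK5, 8702 and 31 for HRAS, 4386 and 1061 for MAP2K1, 5689 and 0 for MAP2K2, 5545 and 467 for MAPK3, and 7741 and 1007 for NGFR. For the difference between lines, in the same order, they were 7206 and 798, 5747 and 403, 3742 and 398, 3744 and 1, 3777 and 1, and 6628 and 368. They were 1437 and 86 for the non-target hairpin, 11095 and 6136 for the lines, and 360 and 0 for genes shared by all 6. For the list calls they were 52 and 49, with a median of 25, so wrong groupings pass many lists too and a single list call is not supported by this count. For non-transduced cells, 2 of 81 splits gave as many, the real one (2459) and 1 with 2494. That split and the next highest (2248, 2245 and 2224) keep both non-transduced SW620 arrays and exchange 1 or both of the SW480 arrays.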
